A study of Mus musculus with 30 samples.

How the data were processed

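The samples were 30 RNA-seq libraries of mouse liver in 10 groups of 3, from 3 experiments with no library in common. Groups and replicate codes (A1 to A16, B1 to B16 and C3 to C8, with gaps) came from the sample titles, and the numbers after the letter do not repeat between groups. The labels give the tissue as liver and the cell type as hepatocyte, without saying whether RNA came from whole liver or isolated hepatocytes. The Kupffer cell gene Clec4f, chosen after its values were seen, was at 29.4 to 86.8 FPKM over all 30 libraries. The labels' protocol describes total RNA, selection of mRNA with poly-T beads and a NEBNext Ultra kit that is not stated to keep strand. Nothing in the labels says that the 3 libraries of a group came from separate animals, so p-values here measure only the spread between these samples, which may be partly technical.

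The values are FPKM, reads per gene scaled for exon length and library size, in 1 table of 54532 genes that the authors deposited with gene coordinates and names. STAR, HOMER 4.11 and the genome builds GRCm38 and mm10 are listed in the submitters' processing notes, without their roles, and the settings, the annotation and the library total used for scaling are not given in the sources used here. Other columns of the table that the authors deposited hold gene coordinates and IDs, treated here as unit other and used only to name and place genes. A symbol was present for 54495 genes, and 53585 had the same coordinates in the GENCODE M21 annotation of GRCm38. For the 219 genes that shared a symbol, the one with the highest mean was kept, which left 54384 symbols. No value column was left unused.

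FPKM are not counts, but the depth behind them could be recovered. Within each library, value times exon length came in steps of 1 read: 99.6% to 99.7% of values up to 100 reads lay within 0.05 read of a whole number. Reads in genes with matching coordinates came to between 13548420 and 24322689 per library, and the totals implied by the scaling to between 13798366 and 26217929. Relative to a median-ratio size factor those implied totals ran only from 0.993 to 1.01, against 0.928 to 1.09 relative to the summed reads, so the scaling of the deposited values followed a median-ratio factor more closely than the summed reads. At these depths a gene at 1 FPKM rests on few reads where its exons are short, so low values carry more counting error. Among the 30 pairs of libraries within groups, the smallest chi-square per degree of freedom of recovered reads was 4.757 and Pearson's r across genes lay between 0.982 and 0.9957, so no pair was treated as 1 library deposited more than once.

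Each experiment was fitted apart with limma 3.58.1 in R 4.3.3 (lmFit, contrasts.fit and eBayes with a mean-variance trend) on log2(FPKM + 1), with 1 term per group and no other covariate, over genes with a mean of at least 1 FPKM in that experiment. Tests were two-sided, and a gene was called at a Benjamini-Hochberg adjusted p under 0.05. All groups of an experiment shared 1 estimate of the spread, with 8 residual degrees of freedom in the experiments with 12 libraries and 4 in the one with 6. Log2 changes are on the log2(FPKM + 1) scale, which understates the change of low genes. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1 was used for tables and figures.

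For 38 gene lists of 5 to 45 members, written from textbook knowledge, 768 list entries were looked up and 3 were not in the table. Lists with at least 5 tested members were tested with fry from limma, adjusted by Benjamini-Hochberg over the lists of a comparison. This test asks whether the genes of a list move, on balance, one way, and does not compare them with other genes. Counts of list members are given at the adjusted p over all genes tested and adjusted over the list alone. Every one of these lists that passed fry also passed camera with a preset correlation of 0.01 between genes. None of them passed camera with a correlation estimated from the data. With the preset correlation camera passed more lists than fry, between 8 and 23 in each comparison. These included 13 for NRASG12V in Nrf2Tg/Tg livers, 23 in Fbp1-delta-Hep livers and 11 for each FBP1 deletion comparison, where fry passed 0.

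The groups, the 11 comparisons, the test, the gene lists and most alternatives were fixed before the data were examined. So was the rule for named genes, which takes in every comparison the manipulated genes, up to 8 called genes with the largest rise and up to 8 with the largest fall whose groups do not overlap (without predicted genes and immune receptor segments), and up to 3 called members of each list. Where a comparison had over 30 such genes, a part was summarised. Genes outside this rule are said to be chosen after their values were seen. One gene that the rule names is not reported here.

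Alternatives fixed in advance were a pseudocount of 0.1, no filter on low values, values rescaled to an equal sum, median-ratio scaling, no mean-variance trend, only the compared groups, sample weights, summing of genes with 1 symbol, camera in place of fry, and leaving out each library in turn. Chosen after seeing the data were limma-voom on the recovered reads, removal of each library's trend over GC content, fits without libraries B12 and B15 and without B1, B2, B12 and B15, a fit of each FBP1 deletion comparison with the code in the column names as a term, and a repeat of list tests on the genes of the full fit where leaving out libraries left a list under 5 tested members. Calls were also counted over other splits of the same libraries. The test was checked on simulated data made from these libraries with 200 changed genes in each of 3 runs. For NRF2 activation without NRAS, 52.6% of genes changed 1.5-fold, 86.7% of those changed 2-fold and 96.9% of those changed 4-fold were called among 10667 genes. The same shares were 26.1%, 74.5% and 95.9% among 10430 genes for FBP1 deletion without NRAS, and 54.1%, 88.1% and 98.9% among 10697 genes for AAV8-FBP1. False calls were 5.14%, 6.13% and 4.74% of calls, in that order, and 0 of 90 unchanged lists passed fry in each. The simulated noise was drawn for each gene apart, and the unchanged lists were random genes. Correlation between the genes of a real list, or a trend shared by the genes of a library, was therefore not checked.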

Results

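Gene expression was measured by RNA-seq in 30 mouse liver libraries, in 10 groups of 3. In the experiment of 12 libraries coded A, livers labelled Nrf2Tg/Tg or Nrf2Act-Hep were either controls (Ctrl) or had received NRASG12V, a mutant RAS oncogene given as a plasmid together with the Sleeping Beauty transposase by hydrodynamic injection, which the labels describe as a way to induce liver cancer. The experiment of 12 libraries coded B crossed the same treatments with the genotypes Fbp1F/F and Fbp1-delta-Hep. In 6 libraries coded C, Nrf2Act-Hep livers were labelled AAV8-Ctrl or AAV8-FBP1, for an adeno-associated virus. NRF2, encoded by Nfe2l2, is a transcription factor that turns on antioxidant and detoxification genes, and FBP1 is the fructose-1,6-bisphosphatase of gluconeogenesis. The series title places the work in the study of a metabolic switch on the way from senescent hepatocytes to liver cancer. The labels do not describe the alleles, do not say whether Ctrl livers were injected, and do not say whether the AAV8 groups had received NRASG12V. They give the cell type as hepatocyte without saying whether RNA came from whole liver or isolated hepatocytes, so how many cells of other types lie behind the matrix, macrophage and endothelial values is not known. Between 13548420 and 24322689 reads per library lay in genes with known coordinates. All means below are FPKM with the SD over n = 3 libraries, and adjusted p-values are from limma for genes and from fry for gene lists.

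The manipulated genes followed the labels for FBP1. Fbp1 (chromosome 13, 62864753 to 62888282, GRCm38) stood at 515 ± 15.4 FPKM in Fbp1F/F Ctrl livers and 2.80 ± 0.106 FPKM in Fbp1-delta-Hep Ctrl livers. After NRASG12V it stood at 634 ± 76.1 FPKM in Fbp1F/F and 5.33 ± 1.72 FPKM in Fbp1-delta-Hep livers. No library of the 2 Fbp1-delta-Hep groups exceeded 6.65 FPKM, and none of the Fbp1F/F groups was below 498 FPKM. In AAV8-FBP1 livers Fbp1 reached 2945 ± 431 FPKM (2461 to 3289 FPKM), against 498 ± 38.7 FPKM (472 to 543 FPKM) in AAV8-Ctrl livers. In the A libraries Fbp1 stood at 467 ± 33.1 FPKM in Nrf2Tg/Tg Ctrl, 417 ± 35.2 FPKM in Nrf2Act-Hep Ctrl, 578 ± 95.9 FPKM in Nrf2Tg/Tg NRASG12V and 512 ± 69.0 FPKM in Nrf2Act-Hep NRASG12V livers. Nfe2l2 (chromosome 2, 75675513 to 75704641) was lower, not higher, in Nrf2Act-Hep Ctrl livers, with 9.13 ± 1.12 FPKM against 16.4 ± 0.947 FPKM in Nrf2Tg/Tg Ctrl livers (log2 change -0.79, adjusted p = 0.0151). That call was lost when library A2 or A6 was left out. With NRASG12V, Nfe2l2 was at 10.4 ± 2.24 FPKM in Nrf2Act-Hep and 14.8 ± 2.42 FPKM in Nrf2Tg/Tg livers (adjusted p = 0.07). Nras (chromosome 3, 103058285 to 103067914) lay between 4.57 and 5.50 FPKM in the group means and was called in no comparison. Whether reads from the NRASG12V plasmid are part of the Nras value is not given in the sources used here.

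**Figure D1:**
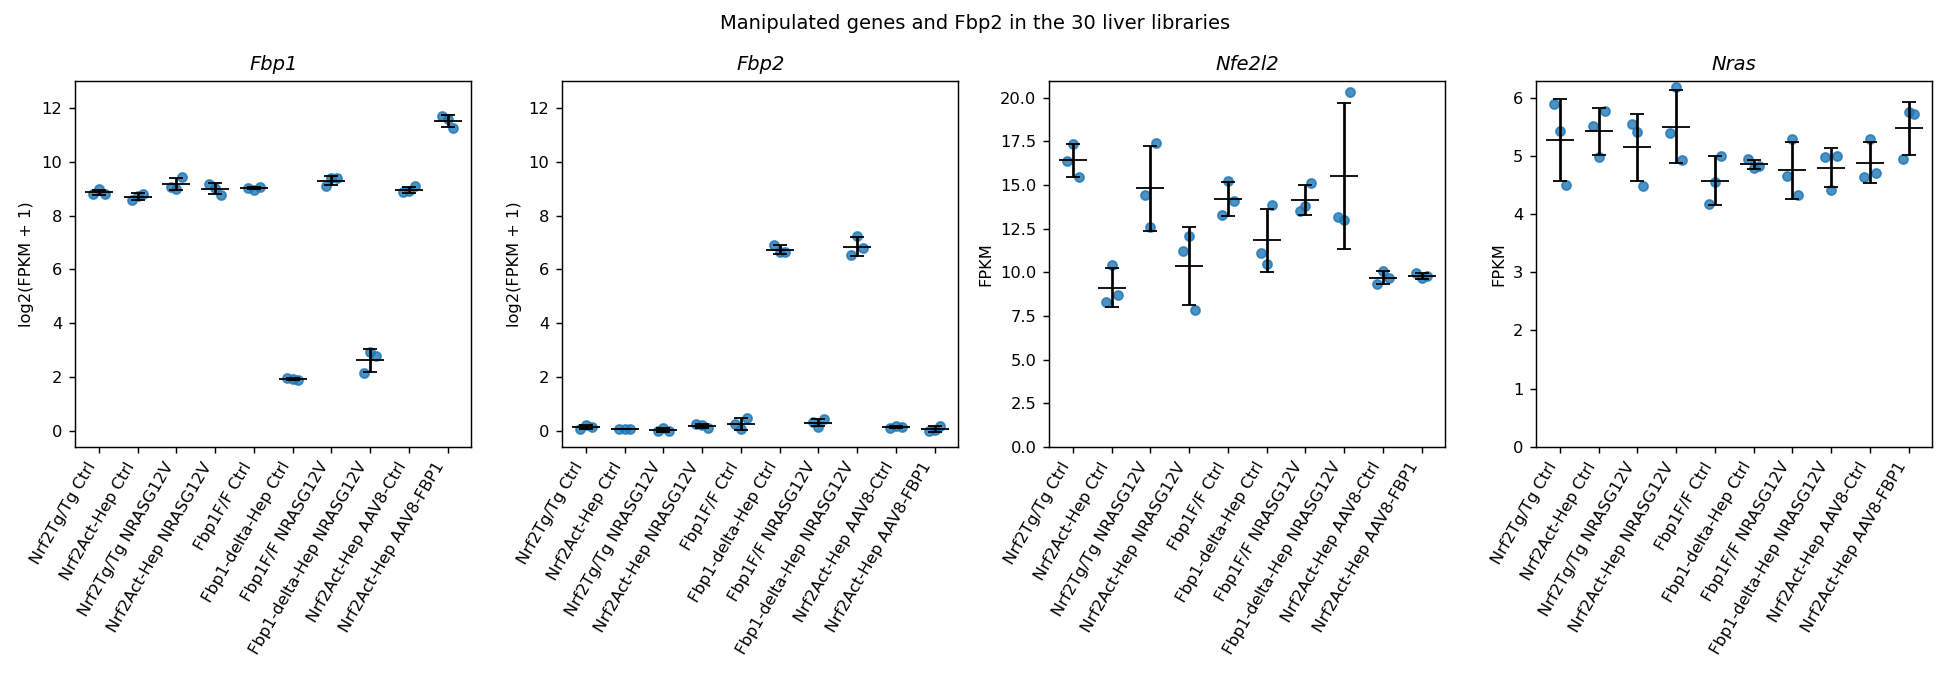
Fbp1 and Fbp2 (log2(FPKM + 1)) and Nfe2l2 and Nras (FPKM) in the 10 groups on the x axis, with 1 point per library and the mean ± SD of 3 libraries. Fbp1 lies near 515 FPKM in Fbp1F/F Ctrl and 2.80 FPKM in Fbp1-delta-Hep Ctrl livers, and Fbp2 is at 106 FPKM in Fbp1-delta-Hep Ctrl livers against 0.198 FPKM in Fbp1F/F Ctrl livers.

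The first comparison asked how livers with the activated NRF2 genotype differed from Nrf2Tg/Tg livers without NRASG12V. Classical NRF2 targets rose strongly. Cbr3, a carbonyl reductase, was at 177 ± 47.6 FPKM in Nrf2Act-Hep Ctrl livers against 1.58 ± 0.972 FPKM in Nrf2Tg/Tg Ctrl livers (adjusted p = 6.58e-06), and the quinone reductase Nqo1 rose 10.8-fold, from 4.82 ± 0.867 to 51.9 ± 1.91 FPKM (adjusted p = 7.26e-06). Cbr1 rose 8.14-fold and the efflux pump Abcc4 rose from 0.761 ± 0.193 to 23.1 ± 6.62 FPKM. Of 35 measured NRF2 target genes, 27 rose and none fell, and 30 rose adjusted over the list alone, with a median log2 change of 1.21 (fry, adjusted p = 6.25e-05). The list had adjusted p = 0.0922 with an estimated correlation.

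Enzymes of the pentose phosphate pathway, which makes NADPH, included 2 that rose, Pgd (17.4 ± 2.94 against 6.72 ± 1.65 FPKM) and Tkt (31.0 ± 3.60 against 17.5 ± 1.85 FPKM), and 5 of 9 adjusted over the list alone, while the list itself missed the threshold (fry, adjusted p = 0.0584). It passed fry without A8 (adjusted p = 0.0149), with rescaled values (0.0452) and with sample weights (0.0138). Asns, the asparagine synthetase induced by amino acid stress, rose 7.84-fold, to 4.69 ± 1.51 FPKM. The 2 groups did not overlap, but Asns varied widely within some groups of the other experiments. It was at 3.77, 4.55 and 0.567 FPKM in the Fbp1F/F Ctrl libraries B1, B2 and B3. In the AAV8-Ctrl libraries C3, C4 and C5 it was at 11.9, 6.10 and 1.87 FPKM. Among drug-metabolising enzymes, Ephx1 rose 2.03-fold, Cyp1a2 rose from 481 ± 39.8 to 990 ± 35.4 FPKM, Cyp2a4 rose from 7.31 ± 9.33 to 307 ± 143 FPKM and Gsta1 rose from 4.03 ± 2.74 to 68.1 ± 23.5 FPKM, whereas Cyp3a11 fell from 1177 ± 306 to 578 ± 53.4 FPKM. The Cyp2a, Gst and Cyp4a families hold near-identical copies whose reads may be split between members, so the single-gene values are uncertain there.

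Genes that fell included 4 of 23 targets of the fatty acid receptor PPARA, without a call for that list (fry, adjusted p = 0.18, but 0.0316 without A3 and 0.0258 with sample weights). The fatty acid hydroxylase Cyp4a14 fell from 156 ± 119 to 2.01 ± 1.71 FPKM (adjusted p = 0.00547), Cyp4a10 fell from 178 ± 55.6 to 33.7 ± 26.2 FPKM, and the fatty acid binding protein Fabp1 fell from 3961 ± 295 to 1782 ± 171 FPKM. The vasopressin receptor Avpr1a fell 4.61-fold (adjusted p = 4.41e-05), the growth factor binding protein Igfbp2 fell 5.12-fold (adjusted p = 0.00408), and Ccnd1, which encodes cyclin D1, fell 3.04-fold. Acute phase genes moved both ways, with Hpx at 1608 ± 16.8 against 2644 ± 267 FPKM and Orm3 at 19.6 ± 0.406 against 3.32 ± 1.69 FPKM. The macrophage gene Marco fell from 7.65 ± 3.59 to 2.33 ± 0.914 FPKM. Genes of stellate cells, fibroblasts and matrix had a median log2 change of -0.32, with 2 of 19 positive and 8 lower adjusted over the list alone (fry, adjusted p = 0.18). That list also passed as lower without A3 (adjusted p = 0.0316) and with sample weights (0.0258), where the interferon-stimulated and acute phase lists passed as lower too (0.0258 for both).

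In all, 515 of 10739 genes were called in that comparison, 392 higher and 123 lower in Nrf2Act-Hep Ctrl livers, and 121 of them by at least 2-fold. The count was 241 without library A2, 244 without A6 and 269 without A7. Fitted on the 2 groups alone it was 339, and with sample weights it was 1413, of which 860 were higher and 553 lower.

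**Figure D2:**
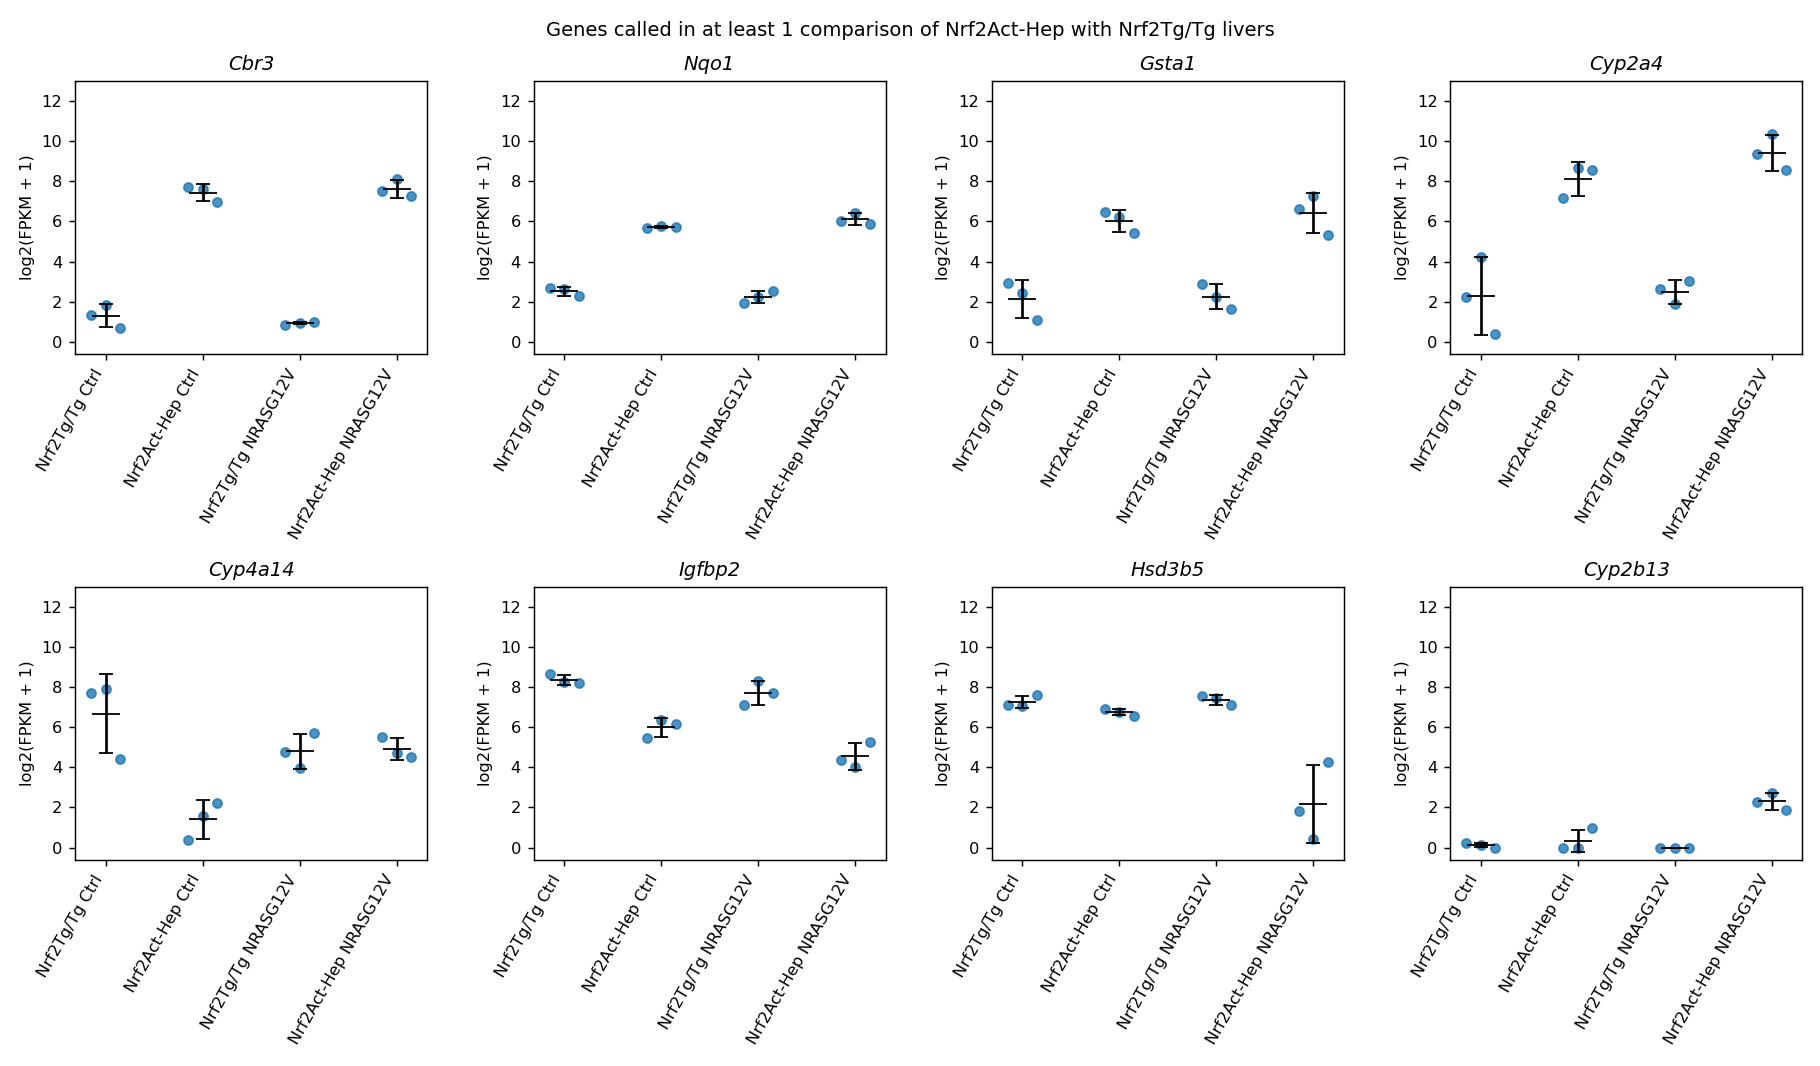
Log2(FPKM + 1) of 8 genes on the y axis in the 4 groups of the A libraries on the x axis, with 1 point per library and the mean ± SD of 3 libraries. Cbr3 and Nqo1 are higher in every Nrf2Act-Hep library (mean Cbr3 177 and 204 FPKM against 1.58 and 0.895 FPKM), Cyp4a14 is low in Nrf2Act-Hep Ctrl livers (2.01 FPKM), and Hsd3b5 is low in Nrf2Act-Hep NRASG12V livers (7.07 FPKM).

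The same genotypes were then compared after NRASG12V. Cbr3 (204 ± 64.9 against 0.895 ± 0.0709 FPKM, adjusted p = 1.93e-06) and Nqo1 (69.4 ± 14.8 against 3.79 ± 1.04 FPKM, adjusted p = 1.93e-06) were again far higher in Nrf2Act-Hep livers, as were the glutathione transferases Gsta2 (210 ± 47.9 against 14.4 ± 2.37 FPKM) and Gstm3 (1902 ± 628 against 148 ± 44.2 FPKM). Of the NRF2 target genes 30 of 35 rose, 32 adjusted over the list alone with 1 lower, and the median log2 change was 1.5 (fry, adjusted p = 2.8e-05, and adjusted p = 0.114 with an estimated correlation). Among 9 pentose phosphate and NADPH genes 4 rose, 5 adjusted over the list alone, including Pgd (2.99-fold), Tkt (1.69-fold) and the malic enzyme Me1 (64.8 ± 9.19 against 32.1 ± 1.28 FPKM) (fry, adjusted p = 0.0142, and adjusted p = 0.456 with an estimated correlation). That list was no longer called without A11 (adjusted p = 0.0609), A12 (adjusted p = 0.0779) or A15 (adjusted p = 0.075).

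Of 20 xenobiotic cytochrome P450 genes 10 rose, 12 adjusted over the list alone with 1 lower, among them Cyp1a2 (742 ± 41.7 against 358 ± 79.9 FPKM) and Cyp2b13, which was at 4.05 ± 1.47 FPKM in Nrf2Act-Hep NRASG12V livers and listed at 0 in all 3 Nrf2Tg/Tg NRASG12V libraries (list by fry, adjusted p = 0.00893, and adjusted p = 0.456 with an estimated correlation). Without A14 or A15 this list had adjusted p = 0.0744 and adjusted p = 0.0785. Cyp2a5 rose 14.1-fold, from 205 ± 85.2 to 2889 ± 447 FPKM (adjusted p = 2.45e-05). The fatty acid transporter Cd36 was 6.75-fold higher and the bile acid enzyme Akr1d1 was 3.32-fold higher. Cd36 was also 2.91-fold higher in Nrf2Act-Hep livers without NRASG12V (adjusted p = 0.0145). Of 21 acute phase genes 9 fell and 1 rose (11 and 1 adjusted over the list alone), with Hpx at 1591 ± 190 against 2916 ± 163 FPKM and Itih4 at 307 ± 27.1 against 480 ± 7.12 FPKM, but Orm3 at 28.8 ± 3.47 against 5.00 ± 2.60 FPKM (list by fry, adjusted p = 0.00946, and adjusted p = 0.456 with an estimated correlation). This list had adjusted p = 0.0581 without A15.

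Sex-biased liver genes changed in that comparison. Of 12 male-biased genes 6 fell, 9 adjusted over the list alone, and all 12 had negative log2 changes (median -1.40). They included the steroid dehydrogenase Hsd3b5 (7.07 ± 9.79 against 164 ± 25.6 FPKM, adjusted p = 0.00154), the anion transporter Slco1a1 (8.47 ± 8.86 against 100.5 ± 3.73 FPKM, adjusted p = 0.00169) and Nudt7. The list passed fry with adjusted p = 0.0351, against adjusted p = 0.63 with an estimated correlation. It missed the threshold without A11 (0.0846), A12 (0.119), A13 (0.058), A14 (0.0849) or A15 (0.0952), with no filter on low values (0.057), with rescaled values (0.0505) and on the 2 groups alone (0.19). Of 5 female-biased genes 3 rose, also adjusted over the list alone, namely Cyp2b13, Cyp2a4 (783 ± 477 against 4.96 ± 2.25 FPKM) and Cyp2b9 (85.4 ± 27 against 0.943 ± 0.561 FPKM) (list by fry, adjusted p = 0.0142, and adjusted p = 0.456 with an estimated correlation). Cyp2a4 was also higher in Nrf2Act-Hep livers without NRASG12V (307 ± 143 against 7.31 ± 9.33 FPKM, adjusted p = 0.0027), so its rise does not depend on NRASG12V. Cyp2b9 and Cyp2b13 are on the xenobiotic cytochrome P450 list too, so these list calls share members. Without A11 or A12 the female-biased list had adjusted p = 0.0656 and adjusted p = 0.0841. Without A14, A15 or A16 fewer than 5 of its genes passed the filter on low values, and with the genes of the full fit kept it had adjusted p = 0.026, 0.0449 and 0.0226. With limma-voom, which used only genes with known coordinates, it had fewer than 5 genes and was not tested. Ddx3y, a Y-linked gene chosen after its values were seen, was at 13.4 to 14.9 FPKM in the 3 Nrf2Act-Hep NRASG12V libraries. Markers of recruited monocytes and lipid-associated macrophages had a median of 0.78 with 9 of 10 positive and 4 higher adjusted over the list alone (fry, adjusted p = 0.276), and the list passed without A16 (median 1.38, adjusted p = 0.00336). The fetal liver and tumour list (median 0.34, adjusted p = 0.102) also passed without A16 (median 0.69, adjusted p = 0.0324). Its members went both ways, with Cbr3 and Cd36 called higher and Akr1c18 called lower (0.875 ± 0.785 against 6.60 ± 1.69 FPKM, adjusted p = 0.00178).

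Several other genes fell strongly. The protease inhibitor Serpina1e fell 25.5-fold, from 6262 ± 162 to 245 ± 248 FPKM (adjusted p = 0.000654), the major urinary protein Mup12 was at 26.9 ± 24.4 against 3977 ± 3749 FPKM, Mup7 at 100 ± 94.0 against 6054 ± 2998 FPKM, and the elongase Elovl3, a member of the male-biased list, at 32.5 ± 37.8 against 302 ± 90.4 FPKM. The pseudogene Serpina4-ps1 was at 5.97 ± 8.10 against 99 ± 51.1 FPKM (log2 change -4.46, adjusted p = 0.0154). The Mup and Serpina1 families also hold near-identical copies, so their single-gene values are uncertain. In glucose metabolism, Ldha, a lactate dehydrogenase subunit, fell 1.56-fold. Ldha was also 1.37-fold lower in Nrf2Act-Hep livers without NRASG12V (adjusted p = 0.00663). Among 22 hepatocyte identity genes 2 rose and 5 fell, including Foxa3 (11.2 ± 7.52 against 37.4 ± 10.7 FPKM), with a median log2 change of -0.17 (fry, adjusted p = 0.385).

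After NRASG12V, 1100 of 10739 genes differed between the genotypes, 527 higher and 573 lower. With values rescaled to an equal sum the split was 749 higher and 358 lower of 1107. The count was 653 without A11, 615 without A12, 511 without A14 and 720 without A15, and 540 on the 2 groups alone. Between the comparison without and the one with NRASG12V, which share no libraries, 250 genes were higher in both, against 19.2 for independent lists, 66 were lower in both, against 6.56, and 1 was called in opposite directions. Both comparisons used the same estimate of each gene's spread, so their calls are not fully independent.

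The next question was what NRASG12V changed within each of these genotypes. In Nrf2Act-Hep livers, fibrillar collagens rose after NRASG12V: Col1a1 was at 10.2 ± 2.42 against 0.867 ± 0.148 FPKM (adjusted p = 0.0238), Col3a1 at 20.4 ± 2.43 against 2.76 ± 0.574 FPKM (adjusted p = 0.0148) and Col1a2 at 5.90 ± 1.60 against 0.951 ± 0.371 FPKM. Of 19 genes of stellate cells, fibroblasts and matrix 10 rose, 16 rose and 1 fell adjusted over the list alone, and 18 had positive log2 changes, with a median of 0.79 (fry, adjusted p = 0.00805, and adjusted p = 0.252 with an estimated correlation). The same list had a median of -0.32 in Nrf2Act-Hep Ctrl against Nrf2Tg/Tg Ctrl livers. The fetal liver and tumour markers Afp (34.2 ± 34.7 against 1.16 ± 0.234 FPKM, adjusted p = 0.0261) and H19 (31.2 ± 27.5 against 0.0402 ± 0.0365 FPKM, adjusted p = 0.0369) rose. Afp stood at 17.6, 74.0 and 10.9 FPKM in A14, A15 and A16. All 18 measured members of that marker list had positive log2 changes, 2 were called and 10 were higher adjusted over the list alone, but the list missed the threshold (median 1.29, fry, adjusted p = 0.0685). It passed fry with a pseudocount of 0.1 (adjusted p = 0.0438), with rescaled values (0.0290), with sample weights (0.0201) and without A16 (0.0173).

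Hsd3b5 fell after NRASG12V in Nrf2Act-Hep livers (7.07 ± 9.79 against 106 ± 11.6 FPKM, adjusted p = 0.0312), as did Mup12 and Mup14. All 12 male-biased genes were lower adjusted over the list alone (median -1.84), but the list missed the threshold (fry, adjusted p = 0.0615). It passed with a pseudocount of 0.1 (adjusted p = 0.0438), with rescaled values (0.0365), with sample weights (0.00948) and without A16 (0.00309). The female-biased list (median 1.3, fry, adjusted p = 0.0713) passed with rescaled values (0.0290), with sample weights (0.0279) and without A8 (0.0399). Fcna, a ficolin of macrophages, fell from 29.4 ± 1.26 to 12.4 ± 0.128 FPKM (adjusted p = 0.000637), and the chemokine Cxcl13 fell 5.71-fold. Clec4f, a Kupffer cell gene chosen after its values were seen, was at 29.4 to 40.3 FPKM in the 3 NRASG12V libraries and 57.8 to 62.6 FPKM in the 3 Ctrl libraries (adjusted p = 0.0991). All 10 markers of recruited monocytes and lipid-associated macrophages had positive log2 changes and were higher adjusted over the list alone (median 1.72), though the list missed the threshold (fry, adjusted p = 0.0615). It too passed with a pseudocount of 0.1 (adjusted p = 0.0438), with rescaled values (0.0290), with sample weights (0.00950) and without A16 (0.00078).

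In total 36 genes were called for NRASG12V in Nrf2Act-Hep livers, 25 higher and 11 lower, and with rescaled values 80 higher and 14 lower of 94. Rescaling moved the median log2 change of all genes by 0.15 in this comparison, by 0.10 for NRASG12V in Fbp1F/F livers and by 0.15 in Fbp1-delta-Hep livers, and by no more than 0.10 elsewhere. Leaving out a library gave 2 (A6), 6 (A7), 3 (A14), 4 (A15) or 319 (A16) calls, and sample weights gave 309, with 150 higher and 159 lower. All Ctrl libraries coded A carry the code E27 in their column names and all NRASG12V libraries the code E21, so the code and the treatment cannot be told apart.

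In Nrf2Tg/Tg livers only 2 genes were called after NRASG12V, Akr1c18 (6.60 ± 1.69 against 0.560 ± 0.444 FPKM, adjusted p = 0.0481) and Asns (3.53 ± 0.806 against 0.598 ± 0.194 FPKM, adjusted p = 0.0481). Both were lost on the 2 groups alone, by limma-voom on recovered reads, after removal of the GC trend and without A1, A2, A11 or A13. Asns also ran from 0.567 to 4.55 FPKM within the Fbp1F/F Ctrl group of the B libraries. The count of calls was 1 without A1, 0 without A2, A11 or A13, 17 without A3 and 6 without A12. No list passed fry there, and 1281 genes had an unadjusted p under 0.05. The matrix list had a median log2 change of 0.46, with 14 of 19 genes higher adjusted over the list alone (fry, adjusted p = 0.174). The test of whether NRASG12V acted differently in the 2 genotypes called 0 of 10739 genes with limma and 0 with limma-voom, with 968 genes at an unadjusted p under 0.05. In it the male-biased genes had a median of -2.22, with all 12 lower adjusted over the list alone (fry, adjusted p = 0.288, but 0.0476 with sample weights and 0.0118 without A16). The recruited monocyte list, with a median of 1.23 and all 10 positive (fry, adjusted p = 0.465), also passed without A16 (median 1.62, adjusted p = 0.0118). The interaction count was 13 without A3, 2 without A7, 3 without A8 and 17 without A16.

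**Figure D3:**
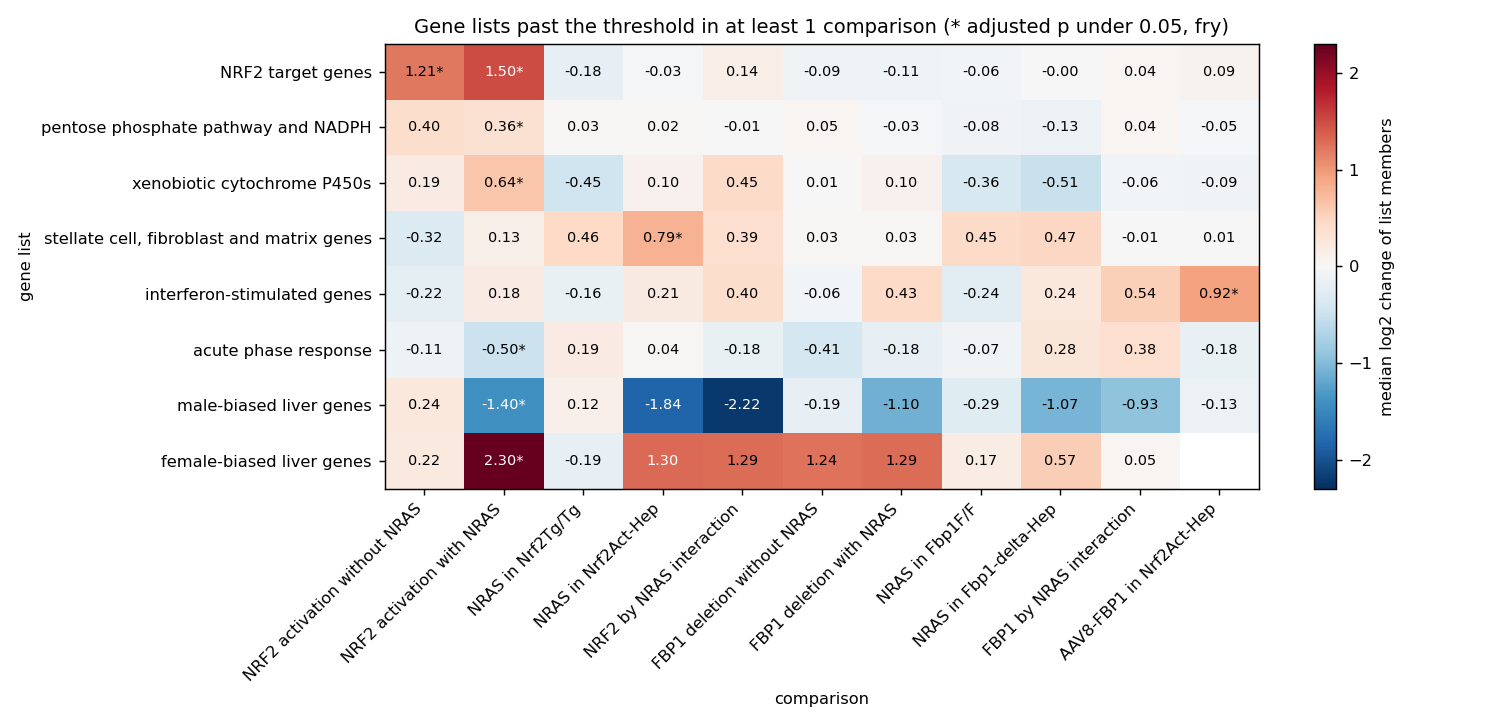
Median log2 change of the members of 8 gene lists on the y axis in the 11 comparisons on the x axis, as colour and as printed values, with an asterisk where fry gave an adjusted p under 0.05. NRF2 target genes stand at 1.21 and 1.5 in the comparisons of Nrf2Act-Hep with Nrf2Tg/Tg livers, matrix genes at 0.79 for NRASG12V in Nrf2Act-Hep livers and interferon-stimulated genes at 0.92 for AAV8-FBP1.

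The B libraries asked what loss of FBP1 in hepatocytes changed. Besides Fbp1 itself (log2 change -7.09, adjusted p = 5.37e-09), Fbp1-delta-Hep Ctrl livers differed in its paralog Fbp2, the muscle isoform, which stood at 106 ± 11.8 FPKM against 0.198 ± 0.173 FPKM (log2 change 6.49, adjusted p = 5.37e-09). Fbp2 lies next to Fbp1 on chromosome 13 (62836877 to 62858422, same strand) and reached 20.6% of the Fbp1 level of Fbp1F/F Ctrl livers. Enpp2, which encodes autotaxin, fell from 17 ± 0.535 to 9.57 ± 0.675 FPKM (adjusted p = 0.019), Cyp2c68 rose from 70.0 ± 15.4 to 243 ± 40.0 FPKM (adjusted p = 0.0465) and Ptgds, a prostaglandin D synthase, rose from 0.332 ± 0.107 to 2.35 ± 0.544 FPKM (adjusted p = 0.0465). Cyp2c68 belongs to a family of near-identical copies, so its value is uncertain.

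These were the only 5 of 10481 genes called, with 830 at an unadjusted p under 0.05, and no list passed fry in the fit with all libraries and no weights. All 22 cholesterol synthesis genes had negative log2 changes (median -0.84), 17 of them adjusted over the list alone, but fry gave adjusted p = 0.308, against 0.0483 with sample weights, where 7 lists passed. For 14 gluconeogenesis genes the median was 0.35 with 12 positive, while fry on the same list, which holds Fbp1, pointed down with adjusted p = 0.457 (0.0289 on the 2 groups alone and 0.0483 with sample weights). With the column code as a term, fry called the RAS-ERK list (median -0.12, adjusted p = 0.00936). The count was 2 without B1, B2 or B7, 3 without B6 and 17 without B3. The libraries B1 and B2 of the Fbp1F/F Ctrl group differed from the other Ctrl libraries coded B. Spearman's rho across genes between deviation and GC content was 0.21 and 0.06 in them, against -0.35 to -0.27 in B3, B6, B7 and B8, and the nuclear RNA Malat1, chosen after its values were seen, was at 13.6 and 8.57 FPKM against 18.9 to 35.4 FPKM. A fit chosen after seeing the data left them out together with B12 and B15, which had a stronger trend with GC content, and called 6 genes, 2 of them among the 5. The count of calls was 31 on the 2 groups alone, 941 with sample weights, 12 without B12 and B15 and 34 with the column code as a term, a code that both groups share evenly.

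With NRASG12V, Fbp1-delta-Hep livers again differed from Fbp1F/F livers in Fbp1 (log2 change -6.68, adjusted p = 5.76e-09) and Fbp2, at 117 ± 29.3 against 0.233 ± 0.116 FPKM (adjusted p = 5.76e-09). These 2 were the only genes called, with 758 at an unadjusted p under 0.05. Genes of fatty acid and triglyceride synthesis had a median log2 change of 0.56, with 16 of 17 positive and 6 higher adjusted over the list alone (fry, adjusted p = 0.101), and interferon-stimulated genes had a median of 0.43, with 11 of 22 higher adjusted over the list alone (fry, adjusted p = 0.133). The fatty acid list passed fry without B15 (adjusted p = 0.0228) and without B12 and B15 (0.0341). So did the male-biased list (0.0228 and 0.0183) and the female-biased list (0.0399 and 0.0183). The fetal liver and tumour list (median 0.39, adjusted p = 0.742) had a median of 0.85 and passed without B12 and B15 (adjusted p = 0.0183). Library B12 of the Fbp1F/F NRASG12V group and B15 of the Fbp1-delta-Hep NRASG12V group stood apart. Their deviations rose with the GC content of genes (Spearman's rho across genes 0.54 and 0.54), and the nuclear RNA Malat1 was at 2.40 and 3.98 FPKM, against 8.57 to 48.7 FPKM in all others. The count of calls was 18 without B15 and 13 without both B12 and B15, a setting chosen after seeing the data, in which Cd36 (log2 change 1.40, adjusted p = 0.04) and Acly, the ATP citrate lyase, (1.2, adjusted p = 0.04) were higher and Nudt7 (-1.46, adjusted p = 0.0193) was lower in Fbp1-delta-Hep NRASG12V livers. Of the 6 libraries only B10 and B14 share a column code, E57, while B11 and B12 carry E59 and B15 and B16 carry E72. With the code as a term on the 2 groups alone, also chosen after seeing the data, Fbp1 was called (log2 change -6.96, adjusted p = 0.0418) and Fbp2 was not (6.22, adjusted p = 0.0635).

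**Figure D4:**
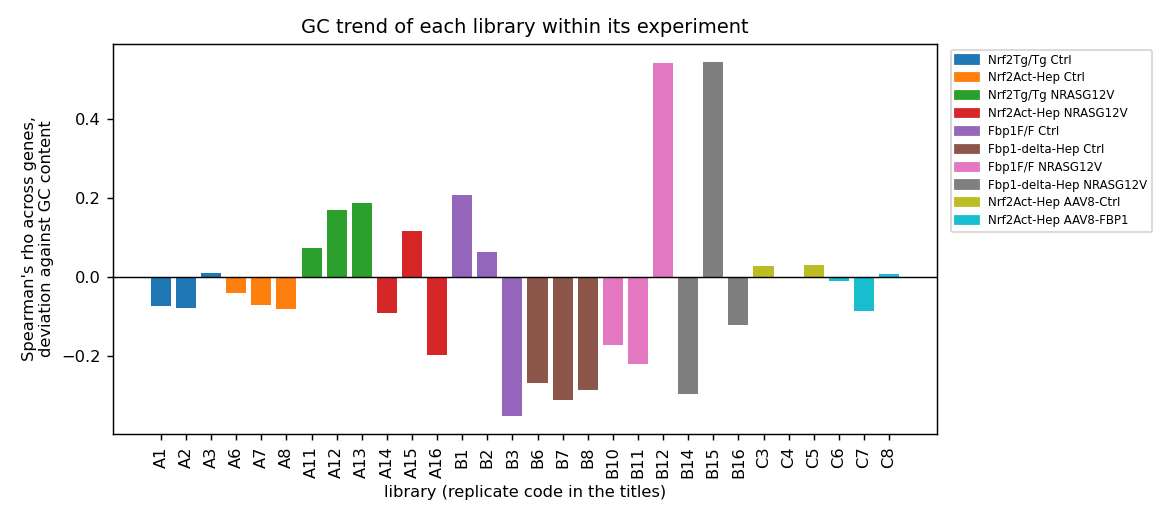
Spearman's rho across genes between the deviation of each library from its experiment and the GC content of the gene, on the y axis, as 1 bar per library on the x axis, coloured by group. B12 and B15 stand at 0.54, and no other library exceeds 0.21.

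NRASG12V itself gave 0 called genes in Fbp1F/F livers with limma and 0 with limma-voom, with 581 at an unadjusted p under 0.05. In Fbp1-delta-Hep livers it gave 0 with limma and 0 with limma-voom, with 938 at an unadjusted p under 0.05. Fetal liver and tumour markers had a median log2 change of 1.06 in both, with all 16 and with 15 of 16 positive and 6 and 12 higher adjusted over the list alone (fry, adjusted p = 0.248 and 0.106). Matrix genes had medians of 0.45 and 0.47, with 7 and 9 of 17 higher adjusted over the list alone (fry, adjusted p = 0.248 and 0.121). In Fbp1-delta-Hep livers both lists passed fry in other settings. Matrix genes had adjusted p = 0.00418 without B15, 0.00362 without B12 and B15, where 8 lists passed, 0.0291 without B1, B2, B12 and B15 and 0.0143 with sample weights. The fetal liver and tumour list had 0.0265, 0.00217, 0.0291 and 0.00960 in the same order and 0.0478 on the 2 groups alone, and in Fbp1F/F livers it passed without B10 (0.0306). In Fbp1-delta-Hep livers hepatocyte identity genes had a median of -0.20 with 2 of 22 positive (fry, adjusted p = 0.121), and the list passed without B15 (adjusted p = 0.0163), without B12 and B15 (0.0172) and with sample weights (0.0143). With rescaled values its median was -0.04 (adjusted p = 0.772). The male-biased list (median -1.07, adjusted p = 0.251) had a median of -1.48 and passed without B15 (adjusted p = 0.0163) and without B12 and B15 (0.0172). In Fbp1-delta-Hep livers 17 genes were called without B15 and 39 without B12 and B15. The 39 included H19 (log2 change 3.16, adjusted p = 0.0273), Akr1c18 (2.3, adjusted p = 0.000641), Afp (1.92, adjusted p = 0.0496) and Col1a1 (1.55, adjusted p = 0.0284) as higher and Hsd3b5 (-5.08, adjusted p = 0.0255) and Elovl3 (-3.89, adjusted p = 0.0159) as lower after NRASG12V. With all libraries none of these was called. H19 then had a log2 change of 2.75 (adjusted p = 0.35), Akr1c18 2.42 (0.255), Afp 1.92 (0.339) and Col1a1 1.04 (0.457). Hsd3b5 had -3.33 (0.473) and Elovl3 -2.66 (0.457). B15 had the highest Hsd3b5 and Elovl3 values of its group, so the calls of these genes depend on leaving it out. One gene was called without B6 and 1 without B8. The test of whether NRASG12V acted differently in the 2 Fbp1 genotypes called 0 genes with limma and 0 with limma-voom, with 415 at an unadjusted p under 0.05, and 1 gene without B6 or without B8. The Ctrl libraries coded B carry the column codes E27 or E12 and the NRASG12V libraries E57, E59 or E72, so code and treatment cannot be told apart there either.

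The C libraries asked what added FBP1 changed in Nrf2Act-Hep livers. Fbp1 was 5.91-fold higher in AAV8-FBP1 livers (adjusted p = 0.00305). Interferon-stimulated genes also rose. The transcription factor Irf7 was at 37.6 ± 0.579 against 11.7 ± 1.23 FPKM (adjusted p = 0.00305), the GTPase Gbp3 at 9.30 ± 0.224 against 2.52 ± 0.428 FPKM (adjusted p = 0.00451), Ifit3 at 17.5 ± 3.32 against 5.66 ± 0.378 FPKM (adjusted p = 0.0168) and the ISG15 protease Usp18 at 10.3 ± 0.331 against 2.45 ± 0.879 FPKM (adjusted p = 0.0274). Of 26 interferon-stimulated genes 13 rose, 24 adjusted over the list alone, and all 26 had positive log2 changes (median 0.92, fry, adjusted p = 0.016, and adjusted p = 0.53 with an estimated correlation). The list missed the threshold without C5 (0.069), C6 (0.0739), C7 (0.119) or C8 (0.0905). Markers of macrophages and Kupffer cells had a median of 0.44 with 16 of 17 positive and 14 higher adjusted over the list alone (fry, adjusted p = 0.108), and endothelial markers had a median of 0.28 with 19 of 19 positive and 12 higher adjusted over the list alone (fry, adjusted p = 0.117). Without C4 both lists passed fry (adjusted p = 0.0203 and 0.0354).

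Other genes that rose were Zbtb16 (6.35 ± 0.463 against 1.43 FPKM), the signalling regulator Rgs16 (14 ± 3.94 against 1.5 ± 1.11 FPKM, adjusted p = 0.0492), the p53 target Phlda3 (1.83 ± 0.147 against 0.471 FPKM) and the stress gene Trib3 (16.1 ± 1.33 against 6.59 FPKM). Tmem150a fell from 61.8 ± 1.56 to 40.2 ± 1.05 FPKM (adjusted p = 0.0168), and Cbs, the cystathionine beta-synthase, fell 1.45-fold. Nfe2l2 was at 9.79 ± 0.154 against 9.70 ± 0.389 FPKM (adjusted p = 0.924), and NRF2 target genes had a median log2 change of 0.09.

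For AAV8-FBP1 40 of 10790 genes were called, 35 higher and 5 lower, with 1685 at an unadjusted p under 0.05. The count was 157 without C3, 7 without C4, 6 without C5, 0 without C7 and 3 without C8, and with sample weights 332, of which 157 were higher and 175 lower. Afp was at 1.83 FPKM in C3 and between 14.6 and 64.5 FPKM in the other C libraries. The 3 AAV8-FBP1 libraries carry the column code E75 and the AAV8-Ctrl libraries E24 or E72, so code and treatment cannot be told apart.

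**Figure D5:**
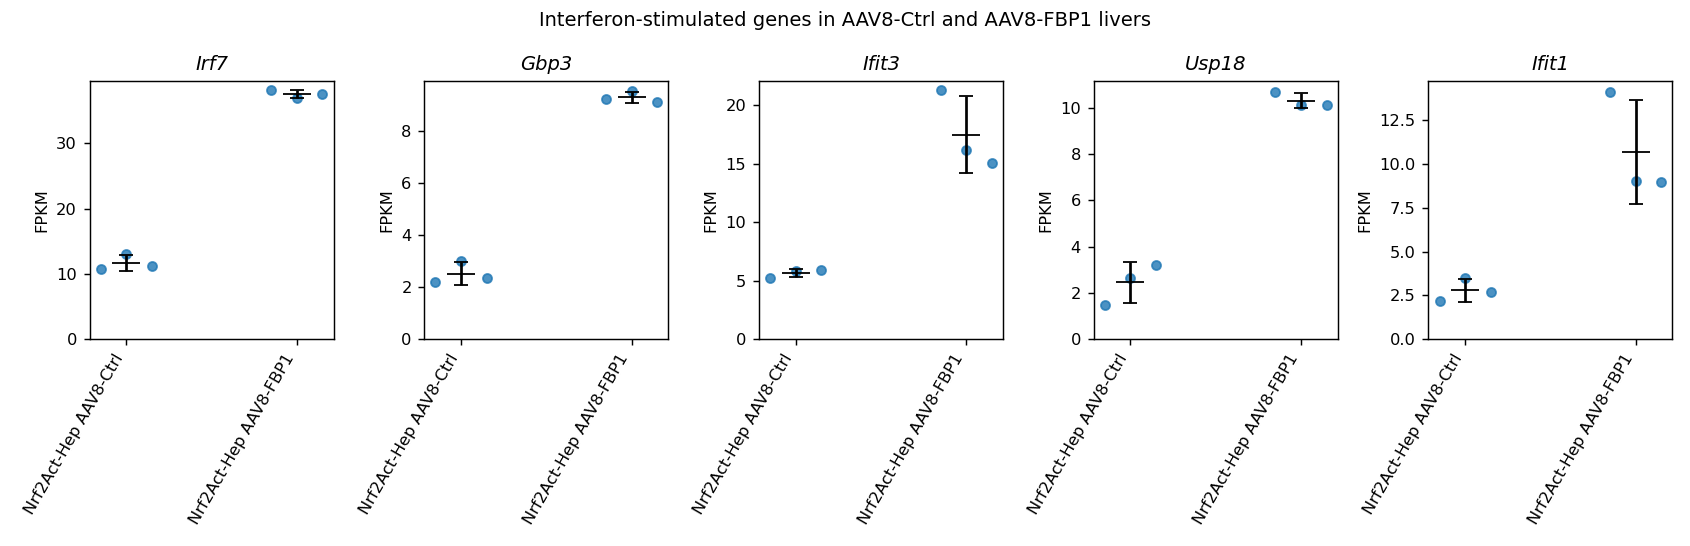
FPKM of 5 interferon-stimulated genes on the y axis in AAV8-Ctrl and AAV8-FBP1 livers on the x axis, with 1 point per library and the mean ± SD of 3 libraries. Irf7 lies at 37.6 FPKM on average in AAV8-FBP1 and 11.7 FPKM in AAV8-Ctrl livers, and Usp18 at 10.3 FPKM against 2.45 FPKM.

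Genes called in one experiment were then tested as lists in another. The 116 measured genes lower in Nrf2Act-Hep Ctrl livers were on balance slightly lower in AAV8-FBP1 than AAV8-Ctrl livers (median log2 change -0.09, 40 positive, fry, adjusted p = 0.00239, and adjusted p = 0.0939 with an estimated correlation). Camera with the preset correlation gave that list adjusted p = 0.105. All tested genes had a median of -0.02 there. The call for that list was lost without C3 (adjusted p = 0.0546), with rescaled values and after removal of the GC trend, and with sample weights its median turned to 0.03. The genes higher in Nrf2Act-Hep Ctrl livers had a median of -0.03 there (adjusted p = 0.214). In Fbp1-delta-Hep Ctrl livers neither list passed (medians -0.08 and -0.08, adjusted p = 0.393 and 0.214). Over 10292 genes, the log2 changes for NRF2 activation and FBP1 deletion had Pearson's r of -0.07 without NRASG12V. With NRASG12V in both comparisons, Pearson's r was 0.42. NRF2 activation without and with NRASG12V had Pearson's r of -0.03 and 0.26 with AAV8-FBP1 over 10483 genes. What lies behind these correlations was not tested. In a test chosen after seeing the data, the 20 measured genes that NRASG12V raised in Nrf2Act-Hep livers had a median of 0.71 after NRASG12V in Fbp1F/F livers and 0.65 in Fbp1-delta-Hep livers, with 19 of 20 positive in each (fry, adjusted p = 0.00766 for both, and adjusted p = 0.0101 and 0.0173 with an estimated correlation). Adjusted over the list alone, 13 and 17 of them were higher. The 11 genes that fell had medians of -0.43 and -0.31 (fry, adjusted p = 0.307 and 0.379). The column code E27 occurs in Ctrl libraries of both the A and the B experiment and in no NRASG12V library. A difference tied to the codes could therefore carry over between the experiments, and it cannot be told apart from NRASG12V here.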

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

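No result met the rules fixed in advance for a closer look, since every group had 3 libraries and both tests of whether NRASG12V acted differently between genotypes called 0 genes, and no test in this part was chosen only after its result was seen. Each comparison of 3 with 3 libraries has 10 splits, too few for a share under 0.05. NRF2 activation called 515 genes without NRASG12V (highest other split 1) and 1100 with it (highest other 0), the real split being the 1 of 10 with as many genes in each. NRASG12V in Nrf2Act-Hep livers called 36 (highest other 0), FBP1 deletion without NRASG12V 5 (highest other 0) and AAV8-FBP1 40 (highest other 2), again 1 of 10 splits in each. For NRASG12V in Nrf2Tg/Tg livers 2 of 10 splits called as many as the real 2 genes (highest other 4). For NRASG12V in Fbp1F/F and in Fbp1-delta-Hep livers, the real count was 0, which every split reaches by construction (10 of 10 in each), so the splits say nothing there. The highest other counts were 3 and 1.

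For FBP1 deletion with NRASG12V, 2 of 10 splits called as many as the real 2 genes, and the split of B11, B14 and B16 against B10, B12 and B15 called 156. A split with so many more calls than the real one points to a structure of these samples, and the cause of that structure was not tested. The tests of a different NRASG12V effect between genotypes also called 0 genes, so 100 of 100 drawn splits in the A and 100 of 100 in the B libraries called as many by construction, which says nothing about chance. The highest counts were 1830 and 72. The 1830 came from a split that kept A14, A15 and A16 together and exchanged the control genotypes, which turns the genotype difference itself into the tested term. The 72 came from a split that again set B11, B14 and B16 apart and also exchanged the control genotypes.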

How the results depend on the processing

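The fits with limma-voom, without the GC trend, without named B libraries, with the column code and with the genes of the full fit kept were chosen only after the results were seen, and the others were fixed before. For NRF2 activation the counts stayed within 1.5 times of 515 and 1100 under the other scalings, a pseudocount of 0.1, no filter, no trend and limma-voom (450 of 482 and 1000 of 1131 voom calls were also main calls). Median-ratio scaling was bound to change little, since the deposited values already followed such a factor. No named gene with a call changed sign under any setting, but calls were lost. Over all comparisons, 273 results for named genes lost their call with 1 library left out, while 867 stayed the same. The counts were 43 and 119 on the compared groups alone, and 47 and 139 with no filter. Fitted on the compared groups alone, counts were 339 and 540 for NRF2 activation without and with NRASG12V, 22 for NRASG12V in Nrf2Act-Hep, 31 for FBP1 deletion without NRASG12V and 4 for NRASG12V in Fbp1-delta-Hep livers; fewer libraries then set the spread. Sample weights gave 1413 for NRF2 activation without NRASG12V, 23 and 309 for NRASG12V in Nrf2Tg/Tg and Nrf2Act-Hep, 941 for FBP1 deletion without NRASG12V, 17 for NRASG12V in Fbp1-delta-Hep livers and 332 for AAV8-FBP1, of which 40 were main calls; the cause was not tested. With no filter, which tests more genes, counts were 7 and 22 for NRASG12V in Nrf2Tg/Tg and Nrf2Act-Hep, 7 and 2 for the differences between Nrf2 and between Fbp1 genotypes, 6 for FBP1 deletion with NRASG12V and 3 for NRASG12V in Fbp1-delta-Hep livers. A pseudocount of 0.1 gave 1 for NRASG12V in Nrf2Tg/Tg and 1 in Fbp1-delta-Hep livers. Values rescaled to an equal sum gave 1 and 94 for NRASG12V in Nrf2Tg/Tg and Nrf2Act-Hep, and 3 and 4 for FBP1 deletion without and with NRASG12V. Limma-voom gave 0 and 19 for NRASG12V in Nrf2Tg/Tg and Nrf2Act-Hep, and removal of the GC trend 0 in Nrf2Tg/Tg and 4 for FBP1 deletion with NRASG12V; the cause was not tested for these. Without B12 and B15 counts were 12 and 13 for FBP1 deletion without and with NRASG12V and 39 for NRASG12V in Fbp1-delta-Hep livers. Without B1, B2, B12 and B15 they were 3 and 9 for NRASG12V in Fbp1F/F and Fbp1-delta-Hep livers and 3 for their difference. FBP1 deletion without NRASG12V then had 6 calls, 2 of them main calls. That setting leaves B3 as the lone Fbp1F/F Ctrl library, which is assumed to vary like the other groups. The column code as a term gave 34 for FBP1 deletion without NRASG12V, 5 of them main calls, and 1 for FBP1 deletion with NRASG12V, where only B10 and B14 share a code. Leaving out 1 library gave 241 to 636 and 511 to 1367 for NRF2 activation without and with NRASG12V, 0 to 17 and 2 to 319 for NRASG12V in Nrf2Tg/Tg and Nrf2Act-Hep, 0 to 17 for their difference, 2 to 17 and 2 to 18 for FBP1 deletion without and with NRASG12V, 0 in every fit for Fbp1F/F, 0 to 17 for Fbp1-delta-Hep, 0 to 1 for their difference and 0 to 157 for AAV8-FBP1. For the genes lower in Nrf2Act-Hep Ctrl livers, the median in AAV8-FBP1 was -0.110 to -0.0726 with 1 library left out (no longer called without C3), -0.0495 with rescaled values and -0.0776 without the GC trend, both no longer called, and 0.0293 with sample weights, where it reversed. Their median in FBP1 deletion was -0.0762 and called with no filter, and the genes higher in Nrf2Act-Hep Ctrl livers had -0.0537 in AAV8-FBP1 and were called with sample weights. The direction of the gluconeogenesis list in FBP1 deletion reversed with camera at the preset correlation, at a median of 0.353 (adjusted p = 0.00767). Camera, unlike fry, compares a list with the other genes. The list holds Fbp1, the deleted gene, so fry's direction says nothing about its other genes. A fit of the list without Fbp1 was not run. None of the 9 lists that passed fry was called by camera with an estimated correlation. No paired analysis was possible because no 2 groups of an experiment share a replicate number. Depth limits the low genes most, since at 1 FPKM a short gene rests on few reads.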

Other observations

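The tests on Fbp2, those on the interferon-stimulated genes and those of Y-linked genes, hepatocyte genes and GC content on the sex-biased pattern were chosen only after the results were seen. Genes outside the naming rule in this part were chosen after their values were seen.

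Nrf2Act-Hep livers with NRASG12V also differed from Nrf2Tg/Tg livers with NRASG12V in smaller groups of genes. Among 22 genes of cholesterol synthesis and uptake 4 rose (7 adjusted over the list alone), including the sterol demethylase Cyp51 (90.3 ± 24.6 against 46.7 ± 4.86 FPKM), Idi1 and Nsdhl, without a call for the list (fry, adjusted p = 0.226). The ERK phosphatases Dusp4 and Dusp6 rose 2.63-fold and 2.14-fold, while Ccnd1 fell 2.35-fold. Without NRASG12V, Dusp4 was already 2.93-fold higher in Nrf2Act-Hep livers (adjusted p = 0.00731) and Ccnd1 3.04-fold lower. The changes of Dusp4 and Ccnd1 therefore do not depend on NRASG12V. The lipase Lpl was at 23.4 ± 8.05 against 7.75 ± 1.69 FPKM, and of the stress genes Trib3 and Sesn2 rose 3.22-fold and 1.73-fold while Atf5 fell 1.55-fold. Of 17 pericentral genes 3 fell and 1 rose (5 and 1 adjusted over the list alone), with the glutamine synthetase Glul at 209 ± 16.8 against 328 ± 56.9 FPKM (fry, adjusted p = 0.4). All 6 red blood cell genes had negative log2 changes, with Alas2 at 17 ± 9.96 against 53.6 ± 2.72 FPKM (fry, adjusted p = 0.0507). That list passed fry with sample weights (adjusted p = 0.0201), after removal of the GC trend (0.0479) and without A16 (0.00667).

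The cell cycle list passed fry in no comparison or setting run. Its genes had medians between -0.17 and 0.20 over the 11 comparisons, and Ccnd1 was the only called member. Senescence and secreted inflammatory factors had a median of 0.69 after NRASG12V in Fbp1-delta-Hep livers, with 10 of 12 positive and 3 higher adjusted over the list alone (fry, adjusted p = 0.121, but 0.0380 with sample weights). After NRASG12V in Nrf2Act-Hep livers that list passed without A16 (adjusted p = 0.0238). Of 21 p53 target genes 4 rose with NRF2 activation and NRASG12V, among them Ephx1 and Dcxr, with a list median of 0.04 (fry, adjusted p = 0.0507). Ephx1 is also on the NRF2 target list. Both genes rose with NRF2 activation without NRASG12V too (2.03-fold and 1.39-fold). With NRASG12V, the p53 list passed for NRF2 activation with sample weights (adjusted p = 0.0377), after removal of the GC trend (0.0390) and without A16 (0.0332). It also passed for NRASG12V in Nrf2Act-Hep livers with rescaled values (0.0290). Glycolysis genes went both ways with NRF2 activation and NRASG12V, 1 higher and 4 lower of 16 (2 and 5 adjusted over the list alone), and none of the 16 was called by FBP1 deletion with or without NRASG12V. FBP1 deletion called only 5 and 2 of 10481 genes without and with NRASG12V, so that count cannot show that glycolysis genes were unchanged.

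Some lists that missed the threshold with all libraries passed fry in single settings. Periportal genes did so for NRF2 activation with NRASG12V (adjusted p = 0.0758, but 0.0296 with rescaled values, 0.0377 with sample weights, 0.0423 after removal of the GC trend and 0.00243 without A13), for NRASG12V in Nrf2Act-Hep livers with rescaled values (0.0365) and for FBP1 deletion with NRASG12V without B11 (0.0447). Pericentral genes passed as lower for NRASG12V in Nrf2Act-Hep livers without A16 (0.0429), and DNA damage genes for NRF2 activation with NRASG12V with rescaled values (0.0296). For FBP1 deletion without NRASG12V the RAS-ERK, cholangiocyte, acute phase, FOXO1 and female-biased lists passed with sample weights (0.0483 for each). For FBP1 deletion with NRASG12V the gluconeogenesis list passed without B14 (0.0323), as lower by fry at a positive median of 0.13. That list holds Fbp1, the deleted gene, so its pass as lower says nothing about its other genes. For NRASG12V in Fbp1-delta-Hep livers oxidative phosphorylation passed as lower without B15 (0.0355) and without B12 and B15 (0.0428), where PPARA targets and red blood cell genes also passed as lower (0.0367 for both) and RAS-ERK genes as higher (0.0282, and 0.0380 with sample weights). Genes of fatty acid synthesis passed there without B15 (0.0451), and as lower for AAV8-FBP1 with limma-voom (0.0171).

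Some genes of the male-biased list spread widely among the Fbp1-delta-Hep NRASG12V libraries and others did not. Hsd3b5 was at 8.82 FPKM in B14 and 1.09 FPKM in B16 but 173 FPKM in B15, against 190, 59.3 and 98.9 FPKM in the Fbp1F/F NRASG12V libraries, and Elovl3 was at 14.2, 14.3 and 198 FPKM in B14, B16 and B15, while Slco1a1 was at 33.2, 31.4 and 35.6 FPKM. Among the AAV8 libraries, Cyp2a4 was at 113, 272 and 337 FPKM with AAV8-Ctrl and 304, 1181 and 1319 FPKM with AAV8-FBP1. Akr1c18 was at 0.078 FPKM in C3 and between 2.28 and 13.5 FPKM in the other AAV8 libraries.

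Fbp2 was at 106 and 117 FPKM in the Fbp1-delta-Hep groups, which is 20.6% and 18.4% of Fbp1 in the Fbp1F/F groups. Reads shared with Fbp1 are argued against, because Fbp2 averaged 0.0578 FPKM in the AAV8-FBP1 libraries, where Fbp1 was highest. Transcription running on from the deleted Fbp1 locus stays open, since Fbp2 lies downstream on the same strand after 6330 bases, and gene-level values hold no junctions with which the 2 cases could be separated. A response of the liver to the loss of FBP1 may also raise Fbp2 and was not tested.

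Interferon-stimulated genes were higher in AAV8-FBP1 livers, and macrophage markers had a median log2 change of 0.44, called without C4 (fry, adjusted p = 0.0203) and not with all libraries (0.108). A larger share of resident macrophages as the whole source is argued against, because the interferon score rose beyond the macrophage score by 0.60 on the log2 scale (SE 0.0911). The lowest AAV8-FBP1 library had a difference of -1.04 and the highest AAV8-Ctrl library one of -1.44. The AAV8-FBP1 and AAV8-Ctrl groups share 0 column codes, so a difference between whatever the codes stand for and the added FBP1 cannot be told apart. A response to the vector or its dose could also raise these genes and was not tested.

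Male-biased genes were lower and female-biased genes higher in Nrf2Act-Hep than in Nrf2Tg/Tg livers with NRASG12V (fry, adjusted p = 0.0351 and 0.0142, and adjusted p = 0.63 and 0.456 with an estimated correlation). Female livers among them are argued against, because the lowest Ddx3y value was 13.4 FPKM and the highest Xist value 0.00293 FPKM. Less hepatocyte RNA is argued against by a median of -0.17 (SD 0.55 over 22 genes) for hepatocyte identity genes, against -1.40 for male-biased genes, and GC content by a median of -1.42 for male-biased genes after the GC trend was removed. Of the female-biased genes, Cyp2a4 also rose with the genotype without NRASG12V (from 7.31 to 307 FPKM), and Cyp2a5 of its family is on the NRF2 target list. Cyp2b9 and Cyp2b13 are shared with the xenobiotic cytochrome P450 list. Both groups with NRASG12V carry the same column code. A weaker male program of hepatocyte expression in these livers is a hypothesis, found and tested on the same data, and the male-biased call was lost without A11, A12, A13, A14 or A15, with no filter on low values (adjusted p = 0.057), with rescaled values (0.0505) and on the 2 groups alone (0.19), and the female-biased call without A11 (0.0656) or A12 (0.0841).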
